A study of Arabidopsis thaliana with 45 samples.

How the data were processed

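RNA sequencing was done on first true leaves of Arabidopsis thaliana. The 45 libraries were made from polyadenylated RNA, isolated with an RNeasy plant kit, by a non-stranded Illumina protocol. They form 15 groups of 3 libraries: Col-0 under long days (16 h of light and 8 h of dark) at D13, D18, D23, D30 and D40, Col-0 under short days (8 h of light and 16 h of dark) at the same 5 days, and tcx5/6 under long days at D13, D18, D23, D30 and D45. The labels give the day in units written DAG, which they do not spell out, and do not say what the replicates were (separate plants, pools or repeated libraries). The p-values below therefore measure the spread between these libraries, which may be technical.

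Per the labels, the authors used cutadapt, Trim Galore 0.6.6, STAR 2.7.1a, HTSeq 2.0 and DESeq2 1.40.1. The genome build is not given in the sources used here, and no positions are printed. The deposited table holds a normalised signal: HTSeq read counts per gene divided by 1 DESeq2 size factor per library. Every value divided by its library's smallest step was whole within 0.01, so whole reads were recovered for each library. The table has 37336 genes and 5 summary entries that name no gene. Of the genes, 37051 matched a locus of the reference annotation, and 9102 of the genes tested have a symbol there. The annotation marks no class of transposable element genes, so no such list was made.

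Reads in genes ranged from 16824317 to 40252818 per library (median 25596039), and 18702 to 23254 genes had a read. A further 45.9 to 48.2% of counted reads lay in no gene (median 47.2%), and 0.111 to 0.238% were ambiguous. Where every library of a group was at 0, a fold is given as a lower bound against 3 reads over the group. Floors cover counting error only, because reads without molecular identifiers are not independent molecules.

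The labels name a non-stranded protocol and give no strand setting for HTSeq. Reads in genes that overlap on opposite strands would be ambiguous if counted without strand, yet few were ambiguous although 7416 of the genes tested overlap such a gene. Counting by strand in a non-stranded library would leave few ambiguous reads and about as many reads in no gene as in genes. Among 370 genes with at least 95% of their exon length under exons of a gene on the opposite strand (partner mean of 500 or more, exon length of 200 or more), the median log2 ratio of read density to the partner was 0.05, and 61.1% lay within 2-fold. Reads of such genes and their partners cannot be told apart, and the share of reads expected from a partner is given where a named gene is affected. Sharing of reads between near-identical gene copies was not tested.

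The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with 1 mean per group, all 15 groups in 1 fit and a mean-variance trend (30 residual degrees of freedom). Genes were kept where at least 3 libraries reached 10, which left 23493 genes. Benjamini-Hochberg adjustment ran within each comparison, and a gene was called at an adjusted p under 0.05. All adjusted p of single genes in the text are from limma. The 8 main comparisons were the last day against D13 in each series, long against short days at D13 and D40, the difference of those age changes between day lengths, tcx5/6 against Col-0 over D13 to D30, and the difference of the D30 change between genotypes. A further 16 comparisons follow the time courses. No Col-0 library exists at D45, so tcx5/6 at D45 is set beside Col-0 at D40 as values without a test.

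The text names genes by a rule: the 5 genes with a symbol and the highest, and the 5 with the lowest, log2 change among those called with a group mean of 100 or more, the targeted and methylation genes TCX5, TCX6, MET1, CMT3, DDM1 and ROS1, and up to 4 called members of each list by the smallest adjusted p. Genes outside the rule are named as chosen after their values were seen. Of 30 gene lists, 27 could be tested: DNA methylation maintenance, RNA-directed DNA methylation, DNA demethylation, the DREAM complex and CXC proteins, DNA replication, mitosis, replication-dependent histones, DNA damage response, leaf growth regulators, leaf senescence, chlorophyll breakdown, autophagy, photosynthesis, chlorophyll synthesis, salicylic acid and immunity, jasmonate, abscisic acid, ethylene, flowering time, circadian clock, anthocyanin and flavonoid synthesis, glucosinolate synthesis, reference genes, flower genes, and markers of the stomatal lineage, of vasculature, and of myrosin cells and trichomes. Methylation-silenced reporter genes, shoot meristem genes and root genes had too few measured members for a test. Lists were tested with camera against all other genes (preset inter-gene correlation of 0.01) and again with an estimated correlation, and with fry. Member counts were also adjusted over the list alone, and they are given where they differ from the counts over all genes tested. The groups, comparisons, rule and lists were fixed before the data were examined.

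Alternatives were a pseudocount of 8 or 0.5, no filter, a stricter filter (50), quantile normalisation, TMM, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, robust eBayes, only the groups compared, leaving out each library in turn, and a replicate block. Added after seeing the data were leaving out genes that overlap a gene on the opposite strand, leaving out D18 from the genotype mean, each short-day group taken as 1 library, and D30 in place of the last day. Quantile normalisation moved the median change of all genes by 0.18 on the log2 scale in the Col-0 long-day age comparison, 0.13 in the tcx5/6 age comparison, 0.24 in the photoperiod by age comparison, 0.12 at D13 and 0.30 at D40, and changes are reported relative to the size factors. Tested on simulated data with 200 changed genes per fold, the main test found 25.0% (photoperiod by age) to 75.3% (genotype mean) of 2-fold changes. Of 4-fold changes it found 60.4 to 90.2%. Camera with the preset correlation gave an unadjusted p under 0.05 for 8 of 8 moved lists and 0 of 8 unmoved ones. The simulated genes were drawn independently, so this does not show how camera treats lists of correlated genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and figures.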

Results

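The series asks how leaf gene expression changes with age, next to loss of DNA methylation named in its title. It follows the first true leaves of Arabidopsis in 3 series of 5 days with 3 libraries each: Col-0 under long days, Col-0 under short days, and the line tcx5/6 under long days. TCX5 and TCX6 are CXC-domain proteins of the DREAM complex, which restrains cell-cycle genes and genes of DNA methylation. Values are normalised read counts, given as mean ± SD with n = 3 libraries per group. Library depth was 16824317 to 40252818 reads in genes.

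The targeted genes were read first, because the labels name a line that lacks them. TCX5 (AT4G29000) was not lower in the libraries labelled tcx5/6: the 15 libraries ranged from 231 to 522, against 271 to 525 in Col-0 long days. In the libraries labelled short days it ranged from 54.1 to 216, and 15 of 15 lay below every Col-0 long-day library. TCX6 (AT2G20110) ranged from 15.7 to 418 in Col-0 long days, from 0 to 142 in the libraries labelled tcx5/6, and from 219 to 2200.0 in those labelled short days. Reads expected from a gene on the opposite strand equalled 14.4% of the TCX5 mean. FT, the leaf-made flowering signal that long days raise, and QQS, a gene of starch metabolism regulated by DNA methylation, were added after their values were seen. FT had 3 or more reads in 12 of 12 Col-0 long-day libraries from D18 on, in 11 of 12 labelled short days, and in 2 of 12 labelled tcx5/6. QQS was at 0 in all 15 libraries labelled short days, and ranged from 252 to 1051 in Col-0 long days and from 559 to 2401 in those labelled tcx5/6. The series are named as labelled throughout, so each direction below that involves short days or tcx5/6 rests on these labels, and TCX5 was not reduced in the line named for its loss.

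**Figure D1:**
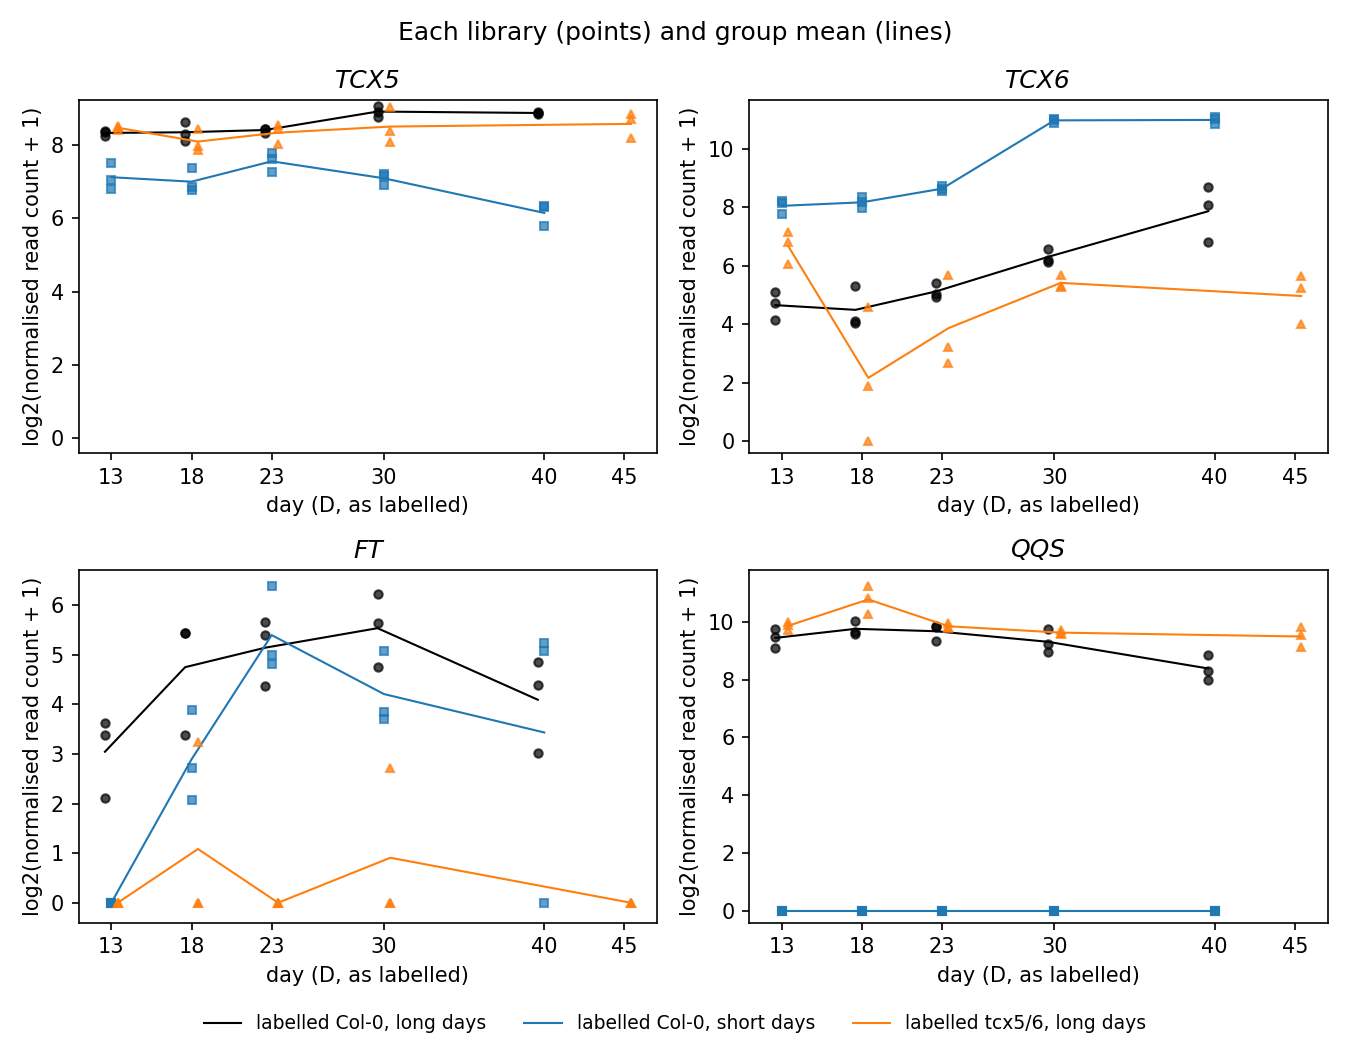
Normalised read counts of TCX5, TCX6, FT and QQS on a log2(value + 1) axis against day, with 1 point per library and lines through group means for the 3 series as labelled. TCX5 lies lowest in the libraries labelled short days, where QQS is at 0 in all 15, and FT is at 0 in 13 of the 15 libraries labelled tcx5/6.

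Col-0 leaves under long days were compared at D40 and D13 to describe leaf ageing. Senescence genes rose: SAG12 (AT5G45890), a cysteine protease of senescing leaves, went from 0 to 193579 ± 62171, at least 137490.0-fold, and NAP, a senescence transcription factor, from 42.0 ± 10.7 to 21995 ± 9998. PR1, a pathogenesis-related protein marking salicylic acid signalling, went from 0 to 56008 ± 39357, at least 39780.0-fold. The germin-like protein gene GER3 fell from 24664 ± 1252 to 0, at least 18412-fold. MET1, the maintenance methyltransferase for CG sites, fell from 1323 ± 79.3 to 28.5 ± 9.19, a 46.3-fold drop (adjusted p = 6.0e-21).

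Many genes of DNA methylation and of the cell cycle fell. Of 11 maintenance genes, 10 fell and 1 did not pass (camera adjusted p = 7.7e-04, adjusted p = 0.083 with an estimated correlation). CMT3, a methyltransferase for CHG sites, fell from 507 ± 84.0 to 59.3 ± 25.7, and DDM1, a chromatin remodeller, from 274 ± 46.4 to 22.0 ± 6.59. Of 21 genes of RNA-directed DNA methylation, 13 fell, 3 rose and 5 did not pass (camera adjusted p = 0.091); AGO4, its effector Argonaute, fell from 915 ± 23.9 to 57.9 ± 36.2. Of 6 demethylation genes, 3 fell and 1 rose (camera adjusted p = 0.28), and ROS1, a DNA glycosylase that removes methylated cytosine, fell from 859 ± 84.6 to 43.4 ± 27.2. In DNA replication 18 of 19 fell and 1 rose (camera adjusted p = 1.1e-06, adjusted p = 0.046 with an estimated correlation), among them MCM2, a helicase subunit, from 723 ± 29.6 to 23.1 ± 10.9. All 21 mitosis genes fell (camera adjusted p = 6.4e-05, adjusted p = 0.083 with an estimated correlation), as did 11 of 15 histone genes, with 1 that rose (camera adjusted p = 0.0010, adjusted p = 0.11 with an estimated correlation). Of the DREAM and CXC genes 9 of 19 rose and 5 fell (camera adjusted p = 0.41). TCX5 rose from 318 ± 16.3 to 464 ± 11.7 (adjusted p = 0.030), a call that ended without Col-0 D13 replicate 2 (0.052) or 3 (0.080) or D40 replicate 1 (0.064) or 3 (0.058). TCX6 rose from 25.2 ± 8.56 to 267 ± 153 (adjusted p = 6.0e-05).

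Many recycling genes rose and photosynthesis genes fell. Of 23 senescence genes 20 rose and 0 fell (camera adjusted p = 1.5e-07, adjusted p = 0.083 with an estimated correlation). All 10 autophagy genes rose (camera adjusted p = 3.7e-06, adjusted p = 0.083 with an estimated correlation), including ATG8A, which coats autophagosomes, from 366 ± 20.14 to 8218 ± 2813. Chlorophyll breakdown had 6 of 8 rising and 1 falling (camera adjusted p = 9.9e-04, adjusted p = 0.17 with an estimated correlation), with SGR1, a magnesium dechelatase, up from 226 ± 8.15 to 22341 ± 7487. All 22 photosynthesis genes fell (camera adjusted p = 8.1e-12, adjusted p = 0.18 with an estimated correlation). LHCB3, a light-harvesting protein, went from 281283 ± 5253 to 2137 ± 1386. All 13 chlorophyll synthesis genes fell (camera adjusted p = 1.7e-08, adjusted p = 0.083 with an estimated correlation). In salicylic acid and immunity 15 of 16 rose (camera adjusted p = 6.7e-06, adjusted p = 0.18 with an estimated correlation), and for abscisic acid 8 of 13 rose and 1 fell (camera adjusted p = 0.033, adjusted p = 0.39 with an estimated correlation). Markers of leaf cell types moved as well: all 8 stomatal lineage genes fell (camera adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation), all 3 myrosin and trichome markers fell (camera adjusted p = 0.011, adjusted p = 0.083 with an estimated correlation), and 5 of 8 vascular markers fell and 1 rose (camera adjusted p = 0.25).

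The remaining lists did not pass the list test. Rising and falling members numbered 2 and 8 of 13 for DNA damage response (camera adjusted p = 0.10), 1 and 7 of 10 for leaf growth (0.10), 7 and 2 of 10 for ethylene (0.065), 6 and 2 of 11 for the clock (0.12), 1 and 4 of 11 for jasmonate (0.57), 4 and 4 of 14 for flowering time (0.98), 4 and 1 of 11 for anthocyanin (0.45) and 7 and 3 of 13 for glucosinolate synthesis (0.16). Of 8 reference genes 4 rose (5 adjusted over the list alone) and 2 fell (0.22). Of 5 flower genes AG rose (0 rose adjusted over the list alone) and SEP3 fell (1.0). The AG call ended without Col-0 D13 replicate 1 (adjusted p = 0.22) or D40 replicate 1 (0.071) or 3 (0.061), and the SEP3 call without D40 replicate 3 (0.078). Of the reporter genes, 2 were measured: QQS fell from 707 ± 153 to 345 ± 110.1 and SDC rose. The SDC call ended without Col-0 D13 replicate 2 (adjusted p = 0.054) or D40 replicate 3 (0.078). A gene on the opposite strand covers 80.2% of the SDC exons. KNAT1, the 1 measured shoot meristem gene, was at 6.04 ± 6.77 at D40 after 0 at D13, a call that ended without any 1 of 5 libraries (adjusted p 0.056 to 0.23). Of the root genes 0 were measured. In all, 7992 genes rose and 8413 fell out of 23493, of which 5821 and 6881 changed at least 2-fold. The split turned to 8517 and 7816 with quantile normalisation and to 8311 and 8150 with TMM. The D40 libraries spread widely, with replicate correlations down to 0.877. In them 3.96 to 5.48% of genes at 20 to 50 in the other libraries of the group were at 0, against 0.283 to 0.619% at D13.

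**Figure D2:**
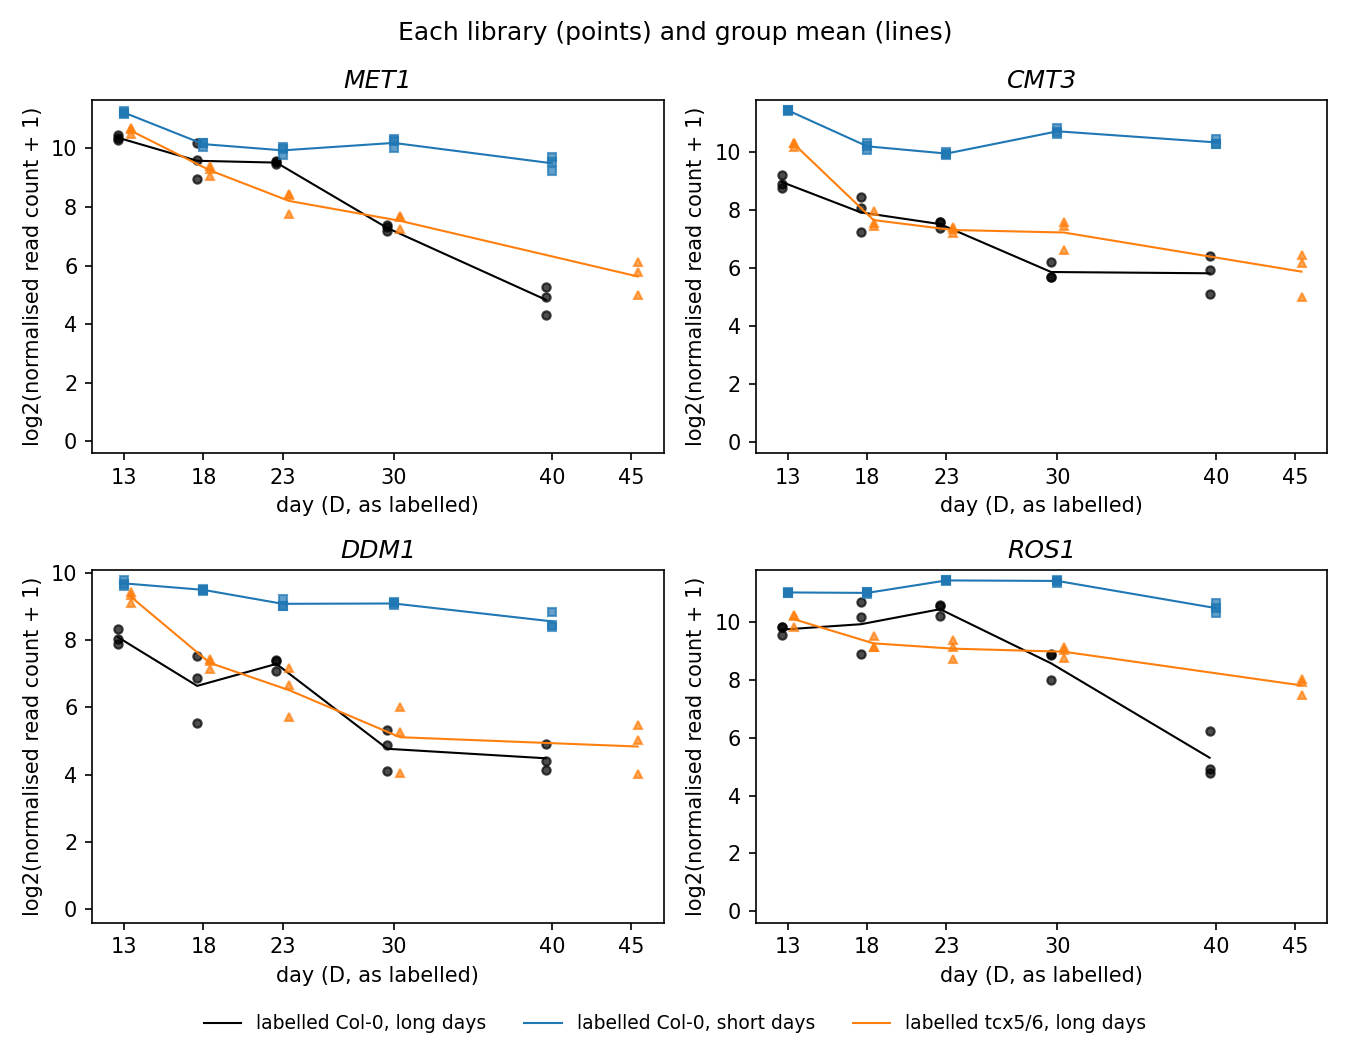
Normalised read counts of MET1, CMT3, DDM1 and ROS1 on a log2(value + 1) axis against day, with 1 point per library and lines through group means for the 3 series as labelled. At D40 the libraries labelled short days lie above those of Col-0 long days for all 4 genes.

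The same comparison in the libraries labelled short days, D40 against D13, asks whether ageing runs alike under another day length. SAG12 rose from 0 to 186833 ± 2229.7, at least 264940.0-fold, and AOX1D, a mitochondrial alternative oxidase, from 0 to 4758 ± 402. GER3 fell from 37303 ± 811 to 0, and FLA2, a fasciclin-like arabinogalactan protein of the cell wall, from 2890.2 ± 153 to 0. MET1 fell 3.32-fold, from 2392 ± 100.3 to 727 ± 116 (adjusted p = 5.8e-08). CMT3 fell from 2794 ± 50.1 to 1301 ± 94.5 and DDM1 from 825 ± 58.2 to 379 ± 65.2, while ROS1 was 2093 ± 33.5 and 1442 ± 169.8 (adjusted p = 0.10, and 0.0022 with quantile normalisation). TCX5 was 140.3 ± 35.9 at D13 and 70.6 ± 14.2 at D40, a fall (adjusted p = 2.4e-04), and TCX6 rose from 267 ± 42.0 to 2046 ± 183.

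Of the 11 maintenance genes 9 fell (camera adjusted p = 0.019, adjusted p = 0.19 with an estimated correlation), and 15 of 21 for RNA-directed DNA methylation (camera adjusted p = 0.0051, adjusted p = 0.13 with an estimated correlation). In DNA replication 10 of 19 fell, 1 rose and 8 did not pass (camera adjusted p = 0.056), with 17 of 21 mitosis genes falling (camera adjusted p = 0.0029, adjusted p = 0.19 with an estimated correlation) and 13 of 15 histone genes (camera adjusted p = 0.0029, adjusted p = 0.18 with an estimated correlation). Leaf growth genes fell in 8 of 10 cases (camera adjusted p = 0.014, adjusted p = 0.13 with an estimated correlation), such as ANT, a regulator of organ growth, from 182 ± 45.6 to 0. Senescence genes rose in 22 of 23 cases (camera adjusted p = 1.5e-08, adjusted p = 0.093 with an estimated correlation), autophagy in 10 of 10 (camera adjusted p = 7.4e-06, adjusted p = 0.13 with an estimated correlation), chlorophyll breakdown in 6 of 8 (camera adjusted p = 5.6e-04, adjusted p = 0.18 with an estimated correlation), salicylic acid and immunity in 16 of 16 (camera adjusted p = 2.5e-05, adjusted p = 0.19 with an estimated correlation), and abscisic acid in 9 of 13 (camera adjusted p = 0.0035, adjusted p = 0.27 with an estimated correlation). Photosynthesis fell in 21 of 22 genes (camera adjusted p = 1.7e-05, adjusted p = 0.39 with an estimated correlation), chlorophyll synthesis in 12 of 13 (camera adjusted p = 2.8e-05, adjusted p = 0.19 with an estimated correlation), and the stomatal lineage in 8 of 8 (camera adjusted p = 0.0028, adjusted p = 0.13 with an estimated correlation). LHCB4.1, an antenna protein, went from 114058 ± 2059 to 25851 ± 728. Of the 23493 genes 7998 rose and 8565 fell, against 7905 and 7885 with only these groups in the fit. The spread of the triplicates over counting noise was flat across read counts. In the 5 groups labelled short days it was 1.05 to 1.12 times as large in genes over 1000 reads as in genes of 20 to 100 reads. At D40 8.07 to 18.4% of genes at 20 to 50 in the other libraries of the group were at 0, against 0.362 to 1.15% at D13, so a 0 at D40 does not show absence. With each group taken as 1 library the count of called genes went from 16563 to 10885.

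In the libraries labelled tcx5/6, D45 was compared with D13. LURP1, a defence gene, rose from 0 to 10029.6 ± 3392, and GolS2, which makes the stress sugar galactinol, from 0 to 7706 ± 2205, at least 7230.4-fold. GER3 fell from 22025 ± 1009 to 0, and EXPA8, a wall-loosening expansin, from 2410.2 ± 119.7 to 0. MET1 fell 31.6-fold, from 1565 ± 105 to 51.2 ± 19.5, CMT3 from 1239.7 ± 67.9 to 63.0 ± 29.0, DDM1 from 631 ± 74.4 to 30.0 ± 14.2 and ROS1 from 1105 ± 167 to 227 ± 44.6. TCX5 was 351 ± 13.2 and 384 ± 84.8 (adjusted p = 0.71). TCX6 fell from 107 ± 38.4 to 33.9 ± 17.4 (adjusted p = 0.025), a call that ended without D13 replicate 2 (0.091) or 3 (0.060) or D45 replicate 2 (0.15), and with quantile normalisation (0.050).

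Cell-cycle lists fell and kept their call with an estimated correlation. DNA replication fell in 18 of 19 genes (camera adjusted p = 3.2e-09, adjusted p = 0.0055 with an estimated correlation), mitosis in 21 of 21 (camera adjusted p = 7.9e-08, adjusted p = 0.023 with an estimated correlation), histones in 14 of 15 (camera adjusted p = 1.5e-07, adjusted p = 0.021 with an estimated correlation), leaf growth in 8 of 10 (camera adjusted p = 0.0038, adjusted p = 0.044 with an estimated correlation) and methylation maintenance in 9 of 11, with 1 that rose (camera adjusted p = 2.6e-04, adjusted p = 0.044 with an estimated correlation). PCNA1, the replication clamp, went from 722 ± 133 to 0. The stomatal lineage fell in 8 of 8 (camera adjusted p = 6.6e-05, adjusted p = 0.028 with an estimated correlation) and myrosin and trichome markers in 3 of 3 (camera adjusted p = 0.0066, adjusted p = 0.044 with an estimated correlation). DNA damage response fell in 8 of 13 (camera adjusted p = 0.0090, adjusted p = 0.087 with an estimated correlation). Senescence rose in 19 of 23 and fell in 1 (camera adjusted p = 1.1e-06, adjusted p = 0.044 with an estimated correlation), with SEN4, a wall-modifying enzyme gene raised in senescence, from 109 ± 22.0 to 5595 ± 3271. Abscisic acid genes rose in 12 of 13 (camera adjusted p = 6.6e-05, adjusted p = 0.13 with an estimated correlation), autophagy in 8 of 10 (camera adjusted p = 2.9e-04, adjusted p = 0.12 with an estimated correlation), chlorophyll breakdown in 7 of 8 (camera adjusted p = 6.9e-04, adjusted p = 0.12 with an estimated correlation), glucosinolate synthesis in 10 of 13 (camera adjusted p = 0.0023, adjusted p = 0.22 with an estimated correlation), salicylic acid and immunity in 10 of 16 (camera adjusted p = 0.0029, adjusted p = 0.31 with an estimated correlation) and the clock in 5 of 11 (camera adjusted p = 0.034, adjusted p = 0.15 with an estimated correlation). Photosynthesis fell in 22 of 22 (camera adjusted p = 7.9e-08, adjusted p = 0.27 with an estimated correlation) and chlorophyll synthesis in 13 of 13 (camera adjusted p = 7.9e-08, adjusted p = 0.087 with an estimated correlation). Of all genes tested 7076 rose and 7962 fell, against 7886 and 7326 with quantile normalisation.

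SAG12 was 54.4 ± 75.5 in the libraries labelled tcx5/6 at D45 and 193579 ± 62171 in Col-0 long days at D40. PR1 was 462 ± 462 and 56008 ± 39357 in the same groups. The days differ and this difference was not tested.

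**Figure D3:**
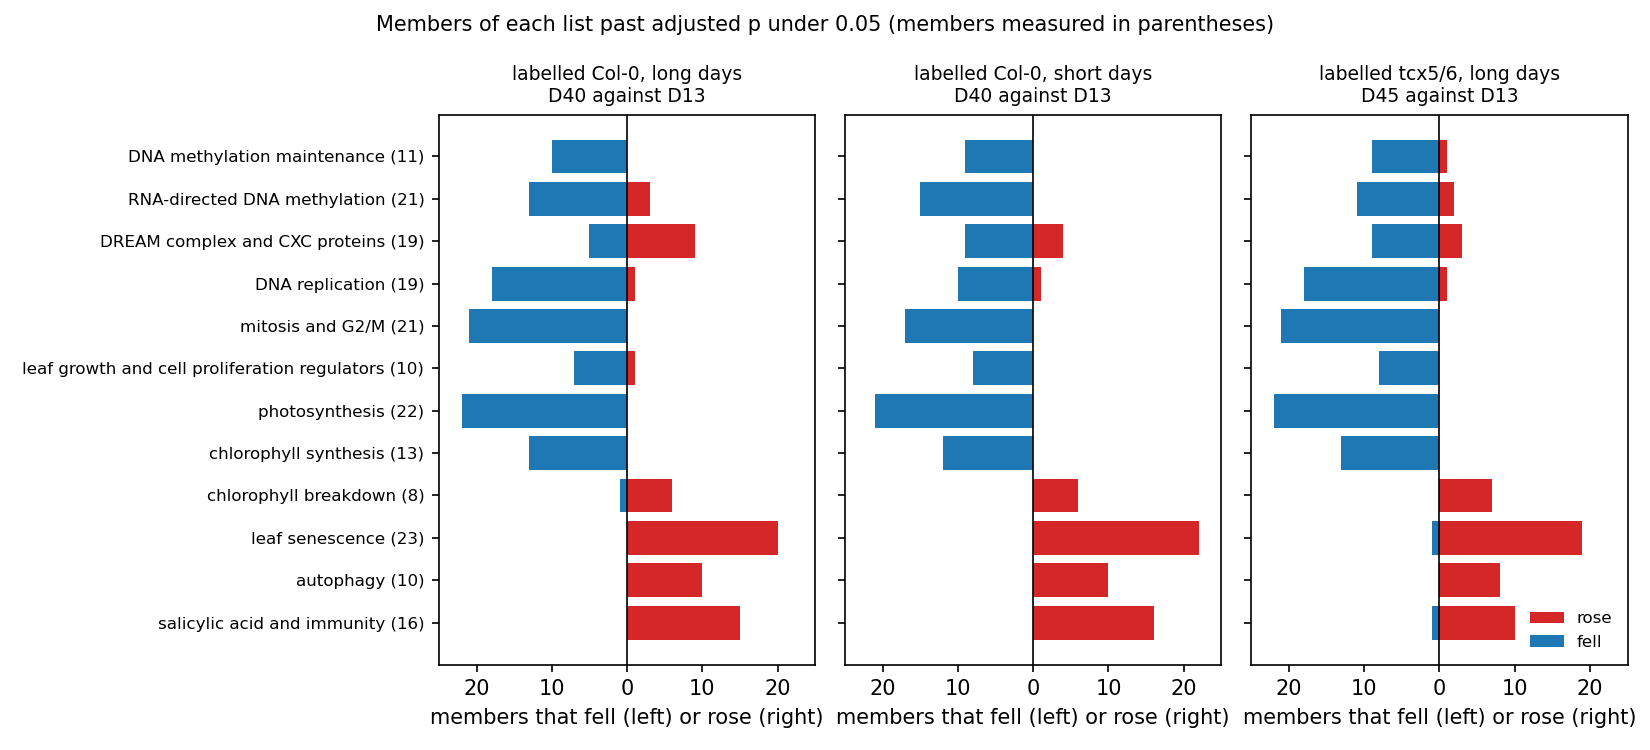
Number of genes that fell (left) and rose (right) with age in each of 12 lists, for the 3 series as labelled. All 22 photosynthesis genes fell in Col-0 long days and in the libraries labelled tcx5/6, and 21 of 22 in those labelled short days.

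The difference between these age changes under long and short days was tested in Col-0. PHI-1 (AT1G35140), a phosphate-induced growth gene, went from 10775 ± 6847 to 18.5 ± 20.203 under long days and from 47.9 ± 19.1 to 7974 ± 221 in the libraries labelled short days. SWEET15, a sucrose exporter of senescing leaves, went from 0 to 2328 ± 3448 and from 1.87 ± 3.25 to 1.58 ± 2.74. The change of MET1 was more negative under long days, with a log2 difference of -3.81 (adjusted p = 2.0e-11), as was that of ROS1 (-3.89), DDM1 (-2.47) and CMT3 (-2.05). TCX5 had a log2 difference of 1.52 (adjusted p = 1.7e-04) and TCX6 of 0.27 (adjusted p = 0.84).

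Photosynthesis genes changed more negatively under long days in 21 of 22 cases (camera adjusted p = 8.7e-10, adjusted p = 0.42 with an estimated correlation), as did chlorophyll synthesis in 12 of 13 (camera adjusted p = 6.4e-06, adjusted p = 0.37 with an estimated correlation), DNA replication in 15 of 19, with 1 the other way (camera adjusted p = 6.4e-06, adjusted p = 0.075 with an estimated correlation), methylation maintenance in 7 of 11 (camera adjusted p = 0.037, adjusted p = 0.38 with an estimated correlation), and myrosin and trichome markers in 2 of 3 (camera adjusted p = 0.031, adjusted p = 0.16 with an estimated correlation). MCM2 was 723 ± 29.6 and 23.1 ± 10.9 under long days, and 606 ± 51.7 and 600.0 ± 130.3 in the libraries labelled short days. Clock genes differed upward in 6 of 11 cases, 8 adjusted over the list alone (camera adjusted p = 9.2e-04, adjusted p = 0.078 with an estimated correlation). Senescence genes differed in both directions, 5 up and 6 down of 23. In total 4795 genes differed upward and 5960 downward, a split that turned to 6323 and 4795 with quantile normalisation. The 10755 called genes fell to 5388 with each short-day group as 1 library and to 4728 with D30 in place of D40.

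At D13, Col-0 libraries from long days were set against those labelled short days to describe young leaves. QQS was 707 ± 153 under long days and 0 in the libraries labelled short days, at least 1002-fold higher. TIL2, a catalytic-subunit relative of DNA polymerase epsilon, was 2.59 ± 2.53 and 1035 ± 29.3, and BSU1, a phosphatase of brassinosteroid signalling, 1.66 ± 2.88 and 466 ± 42.3. TCX5 was higher under long days, 318 ± 16.3 against 140.3 ± 35.9 (adjusted p = 3.9e-05), and TCX6 lower, 25.2 ± 8.56 against 267 ± 42.0. MET1 was lower (log2 difference -0.85), as were CMT3 (-2.47), DDM1 (-1.60) and ROS1 (-1.29).

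DREAM complex and CXC genes were lower under long days in 13 of 19 cases, 14 adjusted over the list alone (camera adjusted p = 2.4e-04, adjusted p = 0.036 with an estimated correlation). ALY1, a DREAM subunit, was 90.0 ± 10.1 and 1059.7 ± 79.1. DNA damage response was lower in 9 of 13 (camera adjusted p = 3.0e-04, adjusted p = 0.036 with an estimated correlation), including RAD54, a recombination protein, at 84.4 ± 6.80 and 1582 ± 71.8. Histones were lower in 12 of 15 (camera adjusted p = 3.0e-04, adjusted p = 0.11 with an estimated correlation), anthocyanin synthesis in 8 of 11 (camera adjusted p = 0.0010, adjusted p = 0.33 with an estimated correlation), salicylic acid and immunity in 7 of 16 (camera adjusted p = 0.030, adjusted p = 0.47 with an estimated correlation), RNA-directed DNA methylation in 9 of 21 (camera adjusted p = 0.035, adjusted p = 0.33 with an estimated correlation), mitosis in 4 of 21 (camera adjusted p = 0.040, adjusted p = 0.37 with an estimated correlation) and glucosinolate synthesis in 7 of 13 (camera adjusted p = 0.046, adjusted p = 0.43 with an estimated correlation). CHS, the first enzyme of flavonoid synthesis, was 23.1 ± 6.25 and 2084 ± 24.5. Higher under long days were abscisic acid in 8 of 13 (camera adjusted p = 0.0015, adjusted p = 0.33 with an estimated correlation), autophagy in 5 of 10 (camera adjusted p = 0.0037, adjusted p = 0.33 with an estimated correlation), chlorophyll synthesis in 6 of 13 (camera adjusted p = 0.0037, adjusted p = 0.37 with an estimated correlation), reference genes in 6 of 8 (camera adjusted p = 0.0037, adjusted p = 0.11 with an estimated correlation) and vascular markers in 4 of 8 (camera adjusted p = 0.023, adjusted p = 0.33 with an estimated correlation). Photosynthesis was higher in 17 of 22 genes (camera adjusted p = 4.1e-04, adjusted p = 0.47 with an estimated correlation), but its median log2 difference went from 1.15 to -0.06 with quantile normalisation. That of chlorophyll synthesis went from 0.70 to 0.0043 and that of reference genes from 0.61 to 0.17. Of all genes 4574 were higher and 4829 lower. With each short-day group as 1 library 4402 genes were called. Their directions match the main fit by construction, because the same libraries gave the differences, and the other groups supply the spread. Col-0 long-day D13 libraries spread widely for some genes, such as XTH18, a wall-modifying enzyme, at 1449 ± 1503, and DDF1, a stress regulator of the DREB family, at 753 ± 792.

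At D40 the same contrast describes old leaves. NCED2 (AT4G18350), an enzyme of abscisic acid synthesis, was 760.0 ± 203 under long days and 3.04 ± 5.26 in the libraries labelled short days, and QQS was at least 432-fold higher. CYP707A3, which breaks down abscisic acid, was 37.8 ± 59.3 and 9247 ± 408. BRCA1, a DNA repair protein, was 2.89 ± 2.83 and 1207 ± 134. MET1 was lower under long days (log2 difference -4.66), as were ROS1 (-5.18), CMT3 (-4.53), DDM1 (-4.07) and TCX6 (-3.12), while TCX5 was higher (2.72).

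DNA replication was lower under long days in 17 of 19 genes (camera adjusted p = 9.9e-10, adjusted p = 0.0022 with an estimated correlation) and DNA damage response in 11 of 13 (camera adjusted p = 8.0e-07, adjusted p = 0.0022 with an estimated correlation). TSO2, a ribonucleotide reductase subunit, was 130.1 ± 63.1 and 5080.0 ± 81.2. Clock genes were higher in 7 and lower in 2 of 11 (camera adjusted p = 4.4e-04, adjusted p = 0.046 with an estimated correlation). Lower under long days were photosynthesis in 21 of 22 (camera adjusted p = 1.7e-07, adjusted p = 0.35 with an estimated correlation), histones in 11 of 15 (camera adjusted p = 1.5e-04, adjusted p = 0.067 with an estimated correlation), methylation maintenance in 8 of 11 (camera adjusted p = 4.4e-04, adjusted p = 0.067 with an estimated correlation), chlorophyll synthesis in 9 of 13 (camera adjusted p = 4.4e-04, adjusted p = 0.33 with an estimated correlation), mitosis in 14 of 21 (camera adjusted p = 0.0014, adjusted p = 0.19 with an estimated correlation), jasmonate in 7 of 11 (camera adjusted p = 0.013, adjusted p = 0.33 with an estimated correlation), anthocyanin in 9 of 11 (camera adjusted p = 0.020, adjusted p = 0.41 with an estimated correlation) and myrosin and trichome markers in 2 of 3 (camera adjusted p = 0.020, adjusted p = 0.11 with an estimated correlation). Higher were autophagy in 9 of 10 (camera adjusted p = 1.5e-04, adjusted p = 0.14 with an estimated correlation), chlorophyll breakdown in 5 of 8 (camera adjusted p = 0.020, adjusted p = 0.35 with an estimated correlation), abscisic acid in 5 of 13 (camera adjusted p = 0.040, adjusted p = 0.53 with an estimated correlation) and reference genes in 5 of 8 (camera adjusted p = 0.040, adjusted p = 0.25 with an estimated correlation). UBQ10, a ubiquitin gene used as a reference, was 143050.0 ± 37787 and 50344 ± 1291. Of all genes 4976 were higher and 6844 lower, against 6994 and 5178 with quantile normalisation. The share of genes at 20 to 50 that were at 0 was 8.07 to 18.4% in the D40 libraries labelled short days, which bears on their values of 0. The 11820 calls became 5874 with only these groups in the fit and 7048 with each short-day group as 1 library.

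The libraries labelled tcx5/6 were compared with Col-0 under long days over D13, D18, D23 and D30, although TCX5 was not lower there and TCX6 was not called. Clock genes also differed between these series and the labels give no hour of harvest. Whether the hour contributes to the differences below was not tested. CHS (AT5G13930) was higher by 6.86 on the log2 scale (adjusted p = 1.1e-13), at 6678 ± 409 against 23.1 ± 6.25 at D13. FLS1, a flavonol synthase, was higher by 6.25 and LDOX, an anthocyanidin synthase, by 6.09. SEN1, a gene induced by darkness and sugar shortage, was lower (log2 difference -7.76), at 3.16 ± 5.47 against 1564 ± 424 at D13. BT2, a nutrient-response regulator, was lower as well (-9.29).

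TCX5 itself differed by -0.15 (adjusted p = 0.27) and TCX6 by -0.61 (adjusted p = 0.11), and TCX6 passed without D18 replicate 1 (0.0043) or D23 replicate 1 (0.020) of tcx5/6. CMT3 was higher by 0.55 (adjusted p = 0.0013) and MET1 lower (log2 difference -0.29, adjusted p = 0.036), a call that ended without any 1 of 8 libraries (0.051 to 0.10) or without D18 (0.095). DDM1 differed by 0.36 (adjusted p = 0.12, and 0.023 to 0.045 without any 1 of 3 libraries) and ROS1 by -0.32 (adjusted p = 0.065, and 0.0025 to 0.048 without any 1 of 3). Anthocyanin genes were higher in 9 of 11 cases (camera adjusted p = 2.7e-06, adjusted p = 0.38 with an estimated correlation). Autophagy was lower in 9 of 10 (camera adjusted p = 0.0020, adjusted p = 0.42 with an estimated correlation), senescence in 15 of 23, with 1 higher (camera adjusted p = 0.016, adjusted p = 0.42 with an estimated correlation), and ethylene in 6 of 10 (camera adjusted p = 0.020, adjusted p = 0.42 with an estimated correlation). EIN3, the ethylene transcription factor, was 1937 ± 183 against 4269.5 ± 185 at D13. Methylation maintenance had 2 higher and 4 lower of 11 (camera adjusted p = 0.81), and DREAM and CXC genes 5 higher and 0 lower of 19, 2 higher adjusted over the list alone (camera adjusted p = 0.36). Of all genes 6144 were higher and 7678 lower, 2086 and 3470 of them at least 2-fold. The split turned to 7191 and 6702 with quantile normalisation. In tcx5/6 D18 replicate 2, 37.0% of genes at 20 to 50 in the other libraries of its group were at 0.

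The difference between genotypes in the change from D13 to D30 was tested next. Here too the hour of harvest is unknown, and its part in the differences was not tested. PCC1 (AT3G22231), a defence-related gene with a daily rhythm, went from 3.21 ± 3.92 to 13528 ± 4506 in the libraries labelled tcx5/6 and from 1684 ± 1866 to 414 ± 351 in Col-0. TOC1, an evening clock gene, went from 419 ± 13.5 to 5908 ± 1028 and from 5103 ± 595 to 4549 ± 383 (adjusted p = 2.3e-20). AN3, a coactivator of leaf cell proliferation, was 249 ± 77.7 at D13 and 28.0 ± 11.4 at D30 in the libraries labelled tcx5/6, and 32.9 ± 11.7 and 83.8 ± 31.7 in Col-0 (adjusted p of the difference = 0.0023). MET1 had a log2 difference of 0.00 (adjusted p = 1.0), CMT3 of 0.07 (adjusted p = 0.94), DDM1 of -0.86 (adjusted p = 0.30), ROS1 of 0.05 (adjusted p = 0.96), TCX5 of -0.55 (adjusted p = 0.22) and TCX6 of -2.91 (adjusted p = 0.021), which did not pass without Col-0 D13 replicate 2 (0.057) or tcx5/6 D13 replicate 2 (0.055).

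Leaf growth genes differed downward in 5 of 10 cases, 6 adjusted over the list alone (camera adjusted p = 9.6e-04, adjusted p = 0.031 with an estimated correlation). Stomatal lineage genes differed downward in 4 of 8 (camera adjusted p = 0.0071, adjusted p = 0.24 with an estimated correlation), DREAM and CXC genes in 5 of 19 (camera adjusted p = 0.0084, adjusted p = 0.24 with an estimated correlation), mitosis in 4 of 21 (camera adjusted p = 0.011, adjusted p = 0.43 with an estimated correlation) and anthocyanin in 3 of 11, with 1 upward (camera adjusted p = 0.033, adjusted p = 0.64 with an estimated correlation). Jasmonate differed upward in 7 of 11 (camera adjusted p = 0.0071, adjusted p = 0.40 with an estimated correlation), salicylic acid and immunity in 6 of 16 (camera adjusted p = 0.011, adjusted p = 0.64 with an estimated correlation) and abscisic acid in 6 and downward in 2 of 13 (camera adjusted p = 0.0053, adjusted p = 0.48 with an estimated correlation). WRKY70, a regulator of salicylic acid defence, went from 72.1 ± 18.9 to 3897 ± 1942 and from 2471 ± 634 to 995 ± 421. RD29A, a drought and cold response gene, went from 1078 ± 123 to 96267 ± 58737 and from 5410.4 ± 907 to 33532 ± 2971. Adjusted over the list alone, 8 abscisic acid genes were upward, 5 stomatal, 6 DREAM and 4 anthocyanin genes downward. Of all genes 3130 differed upward and 2566 downward. The split turned to 2783 and 3058 with TMM.

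Along the time courses, MET1 in Col-0 long days was 809.7 ± 328 at D18, 732 ± 22.9 at D23 and 155 ± 11.4 at D30. In the libraries labelled short days it was 1136 ± 63.8, 981 ± 86.1 and 1172 ± 125, and in those labelled tcx5/6 613 ± 78.7, 302 ± 75.7 and 186 ± 31.4. Against D13, the called genes at D18, D23 and D30 numbered 2278, 5632 and 11931 in Col-0 long days. They numbered 7359, 11449 and 13504 in the libraries labelled short days, and 1320, 4554 and 6261 with each of those groups as 1 library. In the libraries labelled tcx5/6 they numbered 9288, 10800 and 13589. Against Col-0 of the same day, tcx5/6 had 10220 called genes at D13, 11180 at D18, 5815 at D23 and 8244 at D30. At these days CCA1, a morning clock gene, differed by 4.72, 4.45, 1.46 and -1.22 on the log2 scale. TOC1 differed by -3.60, -3.88, -0.23 and 0.38. The labels give no hour of harvest, so these 4 counts may include effects of the hour. Long against short days gave 6969 at D18, 8836 at D23 and 8600 at D30, or 2104, 3488 and 3494 with each short-day group as 1 library. These counts were not tested against each other.

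Age changes were shared between day lengths in Col-0: 5468 genes rose in both (2721 by chance) and 5985 fell in both (3067), while 457 and 769 went opposite ways. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.721 and a Spearman rho of 0.703. The Col-0 change to D30 and the tcx5/6 difference at D30 went opposite ways in 1859 and 1929 genes (1052 and 1036 by chance) and the same way in 533 and 804 (945 and 1154). These comparisons share the Col-0 D30 libraries, which alone gave a covariance of -0.131 in simulations against -0.485 measured. The simulated Pearson r of -0.489 comes from the shared libraries with no gene changed, so it is no measure for the -0.227 found here. In the 20 simulations 66.4% of genes had opposite signs and 0 were called in both comparisons, in either direction. The numbers by chance above take the comparisons as independent, which they are not. The overlap is therefore not free of the shared libraries.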

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

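The explanations weighed here and the splits of the libraries were chosen as tests after the results were seen, while both comparisons of differences were planned.

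A difference between groups drew attention to the age change under long and short days in Col-0, where 10755 genes were called. Other splits of the libraries argue against a grouping by chance only if the 3 libraries of a group are independent samples, which the labels do not say. Of 100 splits 1, the real one, gave as many genes, and the highest other gave 7431. Splits that mix the day lengths within groups raise the spread, which lowers their counts. Lists that differed were photosynthesis (camera adjusted p = 8.73e-10), chlorophyll synthesis and DNA replication (6.35e-06 each), the circadian clock (9.20e-04), myrosin and trichome markers (0.0309) and DNA methylation maintenance (0.0371). With an estimated correlation 0 of these 6 were called. As log2 differences, SWEET15 had 9.31, NCED2 9.24, PR1 8.84, XIE 8.57, TH8 8.03 and TCX5 1.52. Negative differences were PHI-1 -17.39, DDF1 -16.81, XTH18 -15.58, RAS1 -14.38, CYP94B3 -13.93, MET1 -3.81, CMT3 -2.05, DDM1 -2.47 and ROS1 -3.89. SWEET15, NCED2, PR1, TH8 and DDF1 were at 0 in every library of 1 group, so their fitted differences depend on the added count of 1.

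The change from D13 to D30 differed between the libraries labelled tcx5/6 and Col-0 in 5696 genes. By the share of splits chance is not excluded, since 7 of 100 gave as many, with 8228 genes in the highest other. All 6 other splits that gave as many exchanged the genotypes mostly at 1 day, which carries the genotype effect into the difference of changes, so they point to a structure of the samples. Splits that exchanged 1 or 2 of 3 libraries at both days gave 0 to 34 genes, but they mix the genotypes within groups, which raises the spread. In simulated data 11 of 21128 unchanged genes were called in this comparison. The simulation gave each gene 1 spread in all groups and drew libraries independently. It therefore does not cover false calls from uneven spread or from libraries that are not independent. Lists that differed were leaf growth (camera adjusted p = 9.64e-04), abscisic acid (0.00531), jasmonate and the stomatal lineage (0.00711 each), DREAM and CXC genes (0.00844), mitosis (0.0107), salicylic acid and immunity (0.0114) and anthocyanin synthesis (0.0327). With an estimated correlation 1 of these 8 was called, leaf growth. As log2 differences, PCC1 had 13.61, ZAT6 10.24, ERF6 9.55, TCH3 9.38, COR27 9.25, CYP77B1 -9.87, RVE1 -8.75, TYRDC -7.73, XTH6 -7.21, DFR -6.82 and TCX6 -2.91. ZAT6, CYP77B1, TYRDC and DFR were at 0 in every library of at least 1 group, and reads expected from a gene on the opposite strand equalled 38.8% of the TCH3 mean.

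In data outside the comparisons, a median of 47.2% of counted reads lay in no gene.

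For the other comparisons, the splits were too few for a share under 0.05. Age in Col-0 long days called 16405 genes against 567 in the highest other of 10 splits, and the libraries labelled short days 16563 against 22. The libraries labelled tcx5/6 gave 15038 against 10, long against short days 9403 against 82 at D13 and 11820 against 1321 at D40. For the genotype mean 1 of 100 splits, the real one, gave as many as 13822, with 6448 in the highest other. This argues against chance only if the 3 libraries of a group are independent samples, which the labels do not say. The other splits mix the genotypes within groups, which raises the spread and lowers their counts.

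TCX5 lay below every Col-0 long-day library in the libraries labelled short days, QQS was at 0 there, and FT was nearly absent from those labelled tcx5/6. Whether harvest at another time of day lies behind QQS and TCX5 could not be decided. In 9 libraries labelled short days TOC1 lay inside the long-day range, but that range was wide (1642 to 5780). A gene with a daily rhythm can pass the same level at different hours, so such a value does not show the hour. QQS was at 0 and TCX5 low in all 15 libraries labelled short days, whatever their TOC1. Low complexity is argued against for FT, because at most 4.65% of genes at 20 to 50 were at 0 in tcx5/6 D30 and D45. An exchange of the names of the short-day Col-0 series and the tcx5/6 series cannot be told apart from a day length that lowers TCX5 and silences QQS together with a loss of FT in tcx5/6. FT reached 3 reads in 2 of 12 libraries labelled tcx5/6 from D18 on and in 11 of 12 labelled short days, as both would have it, but these values are the pattern itself, and the labels give no seed stock. TCX6 was not low in the series that an exchange would make the mutant: its median was 392 in the libraries labelled short days and 39.2 in Col-0 long days. Whether those reads come from an intact gene was not tested. Of the methylation genes, MET1, CMT3 and DDM1 were higher in the libraries labelled short days than in Col-0 long days at D13 and D40. DREAM restrains such genes, so this goes with an exchange, but a day length that raises them would give the same values. Over D13 to D30 the libraries labelled tcx5/6 had CMT3 called higher, MET1 called lower and DDM1 not called. At D13 alone, the tcx5/6 means of these genes lay above those of Col-0. At least 16-fold apart from Col-0 long days at all 5 days, 56 genes were higher and 5 lower in the libraries labelled short days. In those labelled tcx5/6, 13 were higher and 30 lower at all 4 days compared. Those genes were chosen after their values were seen. A day length that changes them would give the same values, so they do not decide between the explanations. If the names were exchanged, the comparisons of day length would describe the genotype, and those of the genotype would describe day length.

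Clock genes of opposite phase moved against each other with age and between the series. A constant shift of the clock by tcx5/6 is argued against only if leaves of all days were harvested at the same hour. CCA1, a morning gene, was higher in the libraries labelled tcx5/6 at 3 of 4 days and lower at D30 (log2 differences 4.72, 4.45, 1.46 and -1.22). TOC1, an evening gene, went the other way (-3.60, -3.88, -0.23 and 0.38), with small differences at D23 and D30. With different hours a constant shift could give either sign. Harvest at different times of day and a shift of the clock with leaf age cannot be told apart. CCA1 and LHY moved against TOC1 and ELF4 in 11 of 12 comparisons with D13 (4 of 4 in Col-0 long days), but these signs restate the pattern, the comparisons share 3 D13 groups, some changes were near 0 (-0.0511 for TOC1 and ELF4 at D40 in Col-0 long days), and the labels give no hour of harvest.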

How the results depend on the processing

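Each short-day group taken as 1 library, D30 in place of the last day, leaving out D18 and leaving out genes with an opposite-strand overlap were chosen as tests after seeing the data. Under a pseudocount of 8 or 0.5, no filter, a stricter filter, quantile normalisation, TMM, edgeR, DESeq2, robust eBayes, no genes with an opposite-strand overlap and a replicate block, all 8 main counts stayed within 1.5 times their value. With each short-day group as 1 library the count of called genes fell to 10885 for age in the libraries labelled short days, 5388 for photoperiod by age, 4402 for day length at D13 and 7048 at D40. In the time courses it gave 1320, 4554 and 6261 genes at D18, D23 and D30 of the libraries labelled short days against D13, and 2104, 3488 and 3494 for long against short days at those days. Fewer libraries enter these fits, which lowers the counts by construction. D30 in place of the last day gave 4728 genes for photoperiod by age, and the cause was not tested. Only the groups compared gave 5874 for day length at D40 and 11759 at D13. The main fit takes 1 spread per gene from all 15 groups. In genes over 1000 reads the spread over counting noise was 164 in Col-0 long days at D40 and at most 52.8 in any other group. Calls with that group therefore borrow spread from tighter groups. Only the groups compared, which lessens this borrowing but leaves fewer degrees of freedom, gave 14358 instead of 16405 for age in Col-0 long days. Photoperiod by age gave 8691 instead of 10755 and day length at D40 5874 instead of 11820. Of the comparisons without that group, age gave 15790 instead of 16563 (short days) and 14473 instead of 15038 (tcx5/6). Day length at D13 and both genotype comparisons gave more genes. The 2 effects were not told apart. Of 216 list tests 90 were called with camera, 15 with an estimated correlation and 155 with fry, which asks another question. The numbers of the replicates did not pair the libraries (0 of 9 pairs of groups with every correlation over 0.1), and the replicate block left the 90 calls as they were, with 0 lost and 0 gained. With quantile normalisation 2 of 886 named results reversed, EIN3 in photoperiod by age (log2 difference 0.070) and LHCB4.1 at D13 (-0.23), the cause was not tested, and 33 lost and 1 gained a call. With DESeq2 26 of the named results lost a call and with edgeR 27, with only the groups compared 63 of 886 lost and 1 gained a call, and with each short-day group as 1 library 87 of 442 lost it. Without D18 the genotype mean called 11967 genes, and 13 of 117 named results lost their call. The stricter filter tested 874 of the 886 named results and leaving out overlapping genes 697, with 0 calls lost in either. Leaving out overlapping genes removes the affected genes and keeps the values of the others. It therefore does not test how reads from the opposite strand change a call.

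Without 1 library at a time, the counts ranged from 15562 to 16083 for age in Col-0 long days, 15749 to 15906 in the libraries labelled short days and 14006 to 14593 in those labelled tcx5/6. They ranged from 9843 to 10681 for photoperiod by age, 7993 to 8590 for day length at D13, 10635 to 11697 at D40, 13443 to 13903 for the genotype mean and 4899 to 5487 for genotype by age. A group left with fewer libraries takes its spread from all groups. Among named genes 235 such results lost a call and 8 gained one. DESeq2 gave no adjusted p for 7 to 3650 genes per comparison. Depth limits genes near the floor of 3 reads, for which folds are bounds.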

Other observations

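The genes below and the tests of spread were chosen after the values were seen. Between Col-0 long days and the libraries labelled short days, 61 genes were at least 16-fold apart in the same direction at all 5 days, 56 of them higher in the libraries labelled short days. Of the 61, 50 do not overlap a gene on the opposite strand. RAD54, which acts in homologous recombination, ranged from 1 to 89 in Col-0 long days, 780 to 1665 in the libraries labelled short days and 2 to 253 in those labelled tcx5/6. SHOC1 and ATSPO11-1, which act in meiotic recombination, ranged from 0 to 44 and 0 to 10 in Col-0 long days, and from 342 to 991 and 52 to 206 in the libraries labelled short days. HDA18, a histone deacetylase, ranged from 0 to 58 and 675 to 1217, and CLSY4, a remodeller of RNA-directed DNA methylation, from 0 to 30 and 148 to 349. The 5 higher in Col-0 long days were QQS, FLC, MRU1, AT5G01675 and AT5G35480. Between Col-0 and the libraries labelled tcx5/6, 30 genes were at least 16-fold higher in Col-0 at all 4 days compared and 13 in tcx5/6.

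Libraries differed in the share of genes at 20 to 50 in the other libraries of their group that were at 0. That share was 37.0% in tcx5/6 D18 replicate 2, and 18.4, 11.6 and 8.07% in the D40 libraries labelled short days. It was 6.52 and 7.37% in the other tcx5/6 D18 libraries, 4.47 to 5.35% in tcx5/6 D23, and 3.96 to 5.48% in Col-0 long days at D40 against 0.283 to 0.619% at D13. In the D40 libraries labelled short days 0.259 to 0.277% of reads in genes came from organelle genes, against 0.0211 to 0.106% in the other 42.

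The spread among the short-day triplicates was flat: its ratio between genes over 1000 reads and genes of 20 to 100 reads was 1.05 to 1.12 in the 5 groups labelled short days and 1.55 to 12.9 in the other 10. A difference in depth between series is argued against, because after thinning every library to 16824317 reads the highest short-day ratio was 1.199 and the lowest other 1.61. An origin of the 3 libraries in 1 RNA or leaf pool cannot be told apart from leaves of short-day plants that differ less from plant to plant. In genes over 1000 reads the spread over counting noise was lower in the libraries labelled short days than in Col-0 long days at every day (9.15 against 12.8 at D13, 20.006 against 164 at D40). In genes of 20 to 100 reads it was higher at D13 (8.45 against 3.67), D23 (5.52 against 3.07) and D40 (18.7 against 12.7). It was lower at D18 (5.23 against 5.52) and D30 (4.13 against 4.70), so these genes do not decide between the explanations. The highest short-day ratio of 1.12 is the pattern itself, 0 groups labelled long days had a ratio under 1.2, and the labels do not say whether leaves were pooled.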
